A study of Homo sapiens with 57 samples.

How the data were processed

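The data are 57 arrays of the Affymetrix Human Gene 1.0 ST type, 1 for each biopsy: 12 of normal transplants, 17 with IFTA, 8 with DSA-negative and C4d-negative TGP, 9 with DSA-positive and C4d-negative TGP and 11 with CAMR. Per the labels' protocols the cores were kept in RNAlater, tissue that was not kidney was removed, and RNA was used when its integrity number was above 7. The deposited values are log2 expression values. The submitters' processing notes name RMA, oligo and limma, without versions and without saying what each was used for. The meanings of IFTA, CAMR and the capillary inflammation score are the usual ones of the field, while the series title spells out TGP and DSA. Scanner files were not used, so the summary of probes into values could not be changed.

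The table held 29096 probe sets, of which 21214 had an annotation, 19460 of these with 1 gene symbol. Probe sets with several symbols (1754), those without a name (7882) and 24 left out as markers of sex were not tested. For the 768 genes with more than 1 probe set the brightest was kept, which gave 18394 genes. Of the probe sets with 1 symbol, 19429 were found in the reference gene table by their gene number, and 0 symbols had to be updated. Values ran from 2.25 to 14.2 with a median of 6.73, and the medians of single arrays from 6.65 to 6.82. The interquartile range of an array ran from 2.14 to 3.20. The first 2 principal components held 30.3% and 14.5% of the variance. The first followed the signal spread of the arrays, with an absolute correlation of 0.975 with their interquartile range. The highest correlation of any 2 arrays was 0.994. Of the normal arrays, 2 have titles with the same number, and they correlated at 0.983, which is also the median of all pairs of normal arrays (0.983).

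The groups, comparisons, gene lists, thresholds and alternatives were fixed before the data were examined. A linear model with 1 mean per group was fitted to all 57 arrays with limma 3.58.1 in R 4.3.3, with moderated t tests for 10 comparisons (4 groups against normal, 3 TGP groups against IFTA, and the 3 TGP groups against each other) and a moderated F test for any difference. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Named genes followed a rule: against normal the 8 largest rises and 6 largest falls among called genes, in the other comparisons 4 of each, and from each list the 3 members with the smallest p of the F test. Small RNAs without a gene name and uncharacterised loci were skipped. Other list members that are named were chosen after their values were seen.

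Each array received a score for each of 27 gene lists, the mean log2 value of the measured members. The lists were NK cell, T cell, cytotoxic effector, interferon gamma inducible, type I interferon inducible, HLA class I, HLA class II, endothelial marker, endothelial activation, antibody-associated endothelial and NK, B cell, plasma cell, macrophage, granulocyte, mast cell, proximal tubule, loop with distal tubule and collecting duct, podocyte, tubular injury and repair, extracellular matrix and fibrosis, basement membrane, complement, fatty acid oxidation, proliferation and vascular smooth muscle, with immediate-early and heat shock genes as a marker of handling and red cell genes as a marker of blood. Some list members were not analysed here, and B2M is the 1 measured member of the HLA class I list. Scores were compared by permutation tests in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, over every assignment where a group had fewer than 10 arrays and over 100000 random ones otherwise, and adjusted over all 270 tests. The count of members past the threshold when adjusted over the list alone used the limma p-values of that list's members.

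The model, run on simulated data in which genes vary independently, with 100 genes changed for each size among 18394, recovered 80% of 1.5-fold and 96% of 2-fold changes for CAMR against normal, 80% and 98% for DSA-positive TGP, 77% and 95% for DSA-negative TGP and 87% and 99% for IFTA. Overlaps of comparisons that share the normal arrays were set against 100 simulations of unchanged groups and 20 random splits of the normal arrays into 6 and 6. Each count of calls was also set against 99 random regroupings of the same arrays. Figures were drawn with matplotlib 3.10.9, and labels were read with jsonlite 2.0.0.

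The alternatives planned before the data were examined were a fit of the 2 groups alone, array weights, a filter on dim genes (above the table median in at least 8 arrays), the mean of a gene's probe sets, centring each array on its median, leaving out 4 arrays whose titles end in a code that no label explains, averaging the 2 normal arrays with a shared title number, the handling and red cell scores as covariates, and a change of at least 1.5-fold. For lists they were the median over members, leaving out members shared between lists, and limma's camera test with an estimated correlation. Camera tests a list against all other genes, and for the 1 measured gene of the HLA class I list it has no correlation to estimate. A separate limma fit of the list scores with the T cell and macrophage scores as covariates was made to test the endothelial marker list in CAMR against DSA-negative TGP, and was read for the other lists after seeing the data; its p-values are not adjusted. Another 3 were chosen after seeing the data: leaving out 7 narrow arrays, adding the interquartile range of each array as a covariate, and leaving out the 1 array lowest in proximal tubule genes. Narrow arrays were those whose relative log expression had an interquartile range above 0.460, which is 1.5 times the interquartile range of this measure above its upper quartile; the lowest among the 7 was 0.468 and the highest among the others 0.453. The labels gave no dates or batches to test.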

Results

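Gene expression was measured in 57 biopsies of transplanted kidneys, each hybridised to 1 Affymetrix Human Gene ST array, which reads most human transcripts with probes along their exons. The labels placed the biopsies in 5 groups. There were 12 biopsies of transplants described as normal and 17 with non-specific interstitial fibrosis and tubular atrophy (IFTA), the scarring that follows many kinds of graft injury. The other biopsies had transplant glomerulopathy (TGP), a doubling of the glomerular capillary wall. In 8 of them neither donor-specific antibody (DSA) nor the complement fragment C4d was found, in 9 DSA was found without C4d, and 11 with both were called chronic antibody-mediated rejection (CAMR). For the DSA-negative group the label also required a summed score of glomerular and peritubular capillary inflammation above 1. Values were RMA expression levels on the log2 scale for 18394 genes, and the number of arrays limits the precision of every value below. The labels do not say whether each biopsy came from another recipient, so p-values set each difference against the spread between these biopsies. The 2 normal arrays whose titles share a number were counted as separate. With these 2 averaged, 1790 genes were called for CAMR against normal in place of 1992. All errors of differences are standard errors.

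Across the whole design, 1083 genes differed among the 5 groups in limma's moderated F test, with Benjamini-Hochberg adjusted p under 0.05. The 7 arrays called narrow here, set apart by their wide relative log expression, were spread over 4 groups, with 2 each in IFTA, DSA-positive TGP and CAMR, 1 in DSA-negative TGP and 0 among the normal biopsies. A single DSA-positive biopsy had a mean log2 expression of proximal tubule genes of 6.72, against 10.8 in the next lowest of its group.

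**Figure D1:**
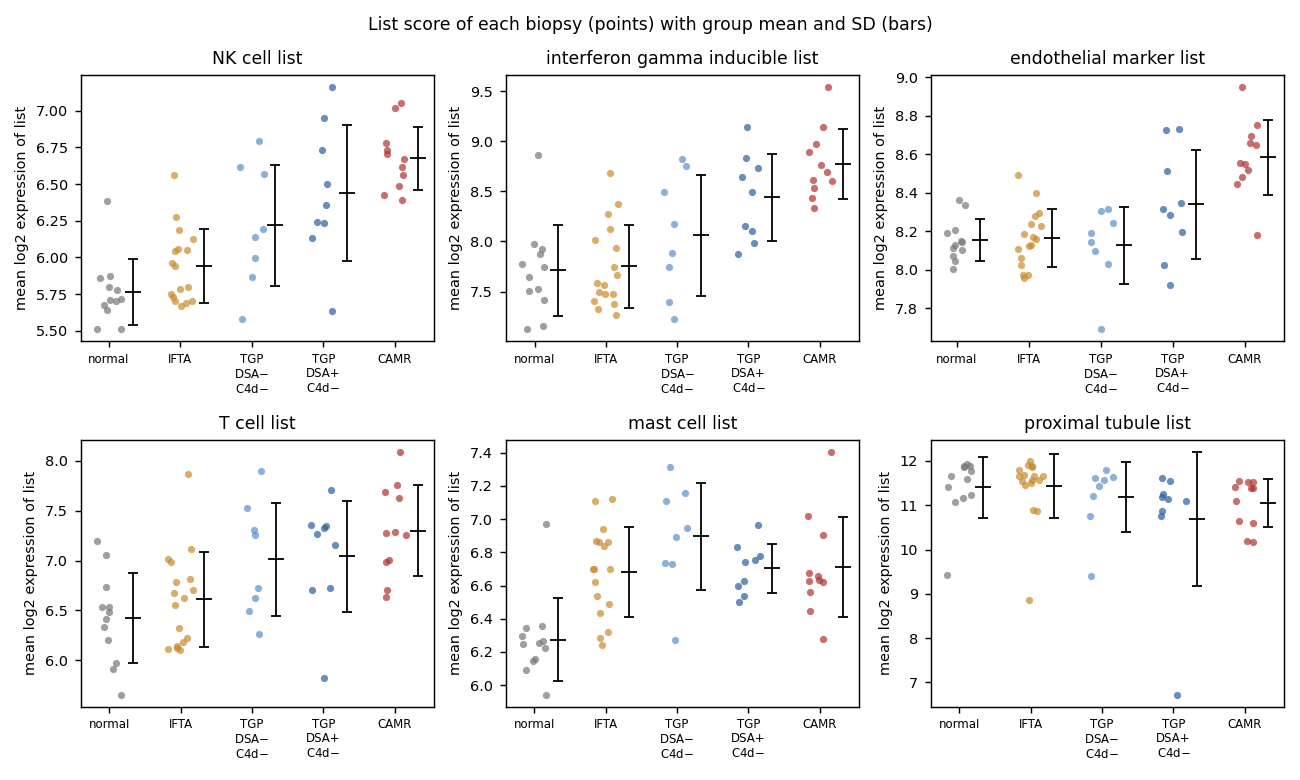
Mean log2 expression of 6 gene lists (vertical axes) in each of the 57 biopsies (points), by group on the horizontal axes, with the group mean and SD as bars. All 11 CAMR biopsies lay above the normal mean for the NK cell, interferon gamma and endothelial marker lists, and 1 DSA-positive biopsy stood at 6.72 in the proximal tubule list.

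The comparison of CAMR with normal transplants asked what accompanies glomerulopathy when both antibody and C4d are present. The largest rises were in transcripts of antibody-secreting cells and of the interferon gamma response. JCHAIN, which links the chains of polymeric IgA and IgM, rose by 3.30 ± 0.77 on the log2 scale (9.84-fold, adjusted p = 0.00239), and IGKC, the constant region of the kappa light chain, rose 6.97-fold (2.80 ± 0.49, adjusted p = 5.18e-05). The chemokines CXCL9, CXCL10 and CXCL11, which attract activated T and NK cells, rose 4.67-fold, 5.17-fold and 5.33-fold. IDO1, which degrades tryptophan, rose by 2.35 ± 0.35 (adjusted p = 4.55e-06), the interferon-induced GTPase GBP5 by 2.33 ± 0.41 and SLAMF7, a surface receptor of NK and plasma cells, by 2.24 ± 0.40. Each of these 8 genes was above the normal mean in 11 of 11 CAMR biopsies. The largest falls were smaller. The secreted glycoprotein OLFM4 fell by 1.30 ± 0.40 (adjusted p = 0.0242), and SCARNA9, a guide RNA of Cajal bodies, by 1.26 ± 0.38. SLC5A11, a myo-inositol transporter, fell by 1.06 ± 0.26, LRRC19 by 1.01 ± 0.23, LYPLAL1 by 0.99 ± 0.28 and the monooxygenase FMO5 by 0.98 ± 0.28. In all, limma called 1992 genes, 1076 higher and 916 lower in CAMR, and 650 of them changed at least 1.5-fold. With each array centred on its median 2460 were called, 1111 higher and 1349 lower, and lower genes were also the majority in the fit of the 2 groups alone (1262 higher, 1420 lower), with array weights (2252 and 2345) and with the dim filter (861 and 985), so the direction of the majority depends on the setting.

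Lymphocyte and NK cell transcripts rose in CAMR. Of the NK cell list, 17 of 20 measured members rose, 0 fell and 3 were not called (18 higher and 0 lower when adjusted over the list alone), and its mean rose by 0.91 ± 0.09 (adjusted p = 0.000245). Among its members were SH2D1B, an adaptor of NK cell signalling (1.64 ± 0.23), GNLY, a lytic granule protein (1.34 ± 0.18), and FCGR3A, the Fc receptor through which NK cells bind antibody-coated cells (2.83-fold). The cytotoxic effector list rose by 0.85 ± 0.15 (adjusted p = 0.00132), with 12 of 15 members higher (14 when adjusted over the list alone), among them the pore-forming PRF1 (1.15 ± 0.19) and the protease GZMB (0.78 ± 0.14). The T cell list rose by 0.88 ± 0.19 (adjusted p = 0.002; adjusted p = 0.0765 with an estimated correlation), and 19 of 21 members rose (20 adjusted over the list alone). They included the T cell receptor subunit CD3D (1.38 ± 0.26) and the checkpoint receptor CTLA4 (0.86 ± 0.14). Plasma cell genes rose by 1.15 ± 0.20 (adjusted p = 0.00184; adjusted p = 0.0773 with an estimated correlation). B cell genes rose by 0.45 ± 0.13 (adjusted p = 0.0117; adjusted p = 0.153 with an estimated correlation). In the plasma cell list 8 of 12 members rose (10 adjusted over the list alone), including the ectoenzyme CD38 (1.33 ± 0.29) and PRDM1, the regulator of plasma cell differentiation (1.31 ± 0.27). In the B cell list 7 of 13 rose (7 adjusted over the list alone), including the receptor subunits CD79A (1.47 ± 0.38) and CD79B (0.44 ± 0.10).

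Myeloid, antigen presentation and interferon genes were also higher. All 20 measured macrophage genes rose (20 adjusted over the list alone), among them the growth factor receptor CSF1R (1.20 ± 0.19), the costimulatory ligand CD86 (1.43 ± 0.23) and the adaptor TYROBP (1.31 ± 0.20). The list difference was 1.07 ± 0.14 (adjusted p = 0.000245). Granulocyte genes rose by 0.58 ± 0.07 (adjusted p = 0.000245), with 7 of 11 members higher (9 adjusted over the list alone), including the formyl peptide receptors FPR1 (0.73 ± 0.11) and FPR2 (0.63 ± 0.11) and the channel AQP9 (1.18 ± 0.19). Most of this list was dim, with 3 of its 11 members kept by the dim filter. Of the interferon gamma list, 22 of 26 measured members rose, 0 fell and 4 were not called (23 higher adjusted over the list alone), including the phospholipase PLA1A (1.32 ± 0.20) and CALHM6 (0.83 ± 0.11). Its mean rose by 1.07 ± 0.17 (adjusted p = 0.000675). HLA class II genes, of the pathway that presents peptides to CD4 T cells, rose by 1.05 ± 0.18 (adjusted p = 0.00135). Of 7 members 6 were higher (7 adjusted over the list alone), including HLA-DOA (1.20 ± 0.17), HLA-DMB (1.03 ± 0.18) and HLA-DMA (0.99 ± 0.16). In the HLA class I list only B2M, the light chain of class I molecules, was measured here. It rose by 0.52 ± 0.15 (list adjusted p = 0.00954, and adjusted p = 0.174 in the camera test). The complement list rose by 0.56 ± 0.12 (adjusted p = 0.00141; adjusted p = 0.174 with an estimated correlation), with 7 of 16 members higher (8 adjusted over the list alone). Those 7 were C1QA, C1QB, C1QC, C1R, C2, C3AR1 and C5AR1, and the C1Q chains are also members of the macrophage list. With the T cell and macrophage scores as covariates the direction of the complement list turned (-0.21 ± 0.07, limma p = 0.00288). Type I interferon genes did not pass as a list (0.39 ± 0.16, adjusted p = 0.0844), although 5 of 22 members rose (8 adjusted over the list alone), including the antiviral OAS2 (1.03 ± 0.23) and MX2 (0.94 ± 0.22). That list passed without the narrow arrays (0.50, adjusted p = 0.0305). In that setting 17 lists passed as higher and 1 as lower, against 17 and 2 with all arrays, so some other lists no longer passed.

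Endothelial lists rose in CAMR. Of the endothelial marker list, 13 of 21 measured members rose, 0 fell and 8 were not called (14 higher and 0 lower when adjusted over the list alone), including ENG, a co-receptor of TGF-beta (0.69 ± 0.09), the guidance receptor ROBO4 (0.64 ± 0.09) and the nitric oxide synthase NOS3 (0.60 ± 0.09). The list rose by 0.43 ± 0.07 (adjusted p = 0.000245). The endothelial activation list rose by 0.70 ± 0.09 (adjusted p = 0.000245), with 10 of 15 members higher (12 adjusted over the list alone). They were led by the leukocyte adhesion molecule SELE (1.69 ± 0.24), the chemokine-binding receptor ACKR1 (1.63 ± 0.23) and MALL (0.79 ± 0.13). The antibody-associated list, endothelial and NK cell transcripts written down before the data were examined, rose by 0.78 ± 0.09 (adjusted p = 0.000245) with 22 of 28 members higher (25 adjusted over the list alone), including the cytokine receptor subunit IL18RAP (1.14 ± 0.16). Mast cell genes rose by 0.44 ± 0.12 (adjusted p = 0.006; adjusted p = 0.0782 with an estimated correlation), and 4 of 7 members rose (5 adjusted over the list alone). They included the protease CPA3 (1.15 ± 0.36) and FCER1A, a subunit of the IgE receptor (0.75 ± 0.26).

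Part of these differences went with leukocyte content. The T cell and macrophage scores themselves rose in CAMR, so as covariates they may remove differences that belong to the groups. With the T cell and macrophage scores as covariates, the cytotoxic effector (0.10 ± 0.09, limma p = 0.268), HLA class II (0.13 ± 0.13, limma p = 0.312), B cell (0.17 ± 0.10, limma p = 0.112), plasma cell (0.39 ± 0.20, limma p = 0.0506) and mast cell (0.14 ± 0.12, limma p = 0.237) lists were no longer under an unadjusted p of 0.05. B2M (-0.04 ± 0.14, limma p = 0.775) was not either. The antibody-associated (0.44 ± 0.10, limma p = 1.94e-05), NK cell (0.34 ± 0.09, limma p = 0.000205), endothelial marker (0.34 ± 0.09, limma p = 0.000454), granulocyte (0.33 ± 0.08, limma p = 0.000201), endothelial activation (0.24 ± 0.08, limma p = 0.0047) and interferon gamma (0.30 ± 0.14, limma p = 0.0311) lists were under 0.05.

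The distal nephron and fatty acid oxidation lists fell, and neither passed with an estimated correlation or with the handling covariates below. The loop, distal tubule and collecting duct list fell by 0.31 ± 0.11 (adjusted p = 0.0393; adjusted p = 0.38 with an estimated correlation), with 2 of 19 members lower (2 adjusted over the list alone). These were the potassium channel KCNJ1 (-0.61 ± 0.17) and the proton pump subunit ATP6V0D2. Fatty acid oxidation genes fell by 0.41 ± 0.10 (adjusted p = 0.00461; adjusted p = 0.235 with an estimated correlation), with 6 of 17 members lower (10 adjusted over the list alone). Among them were ACAA2 (-0.58 ± 0.16), HADHB (-0.45 ± 0.11) and HADHA (-0.34 ± 0.10), enzymes of the beta-oxidation cycle. With the T cell and macrophage scores as covariates the distal nephron list turned (0.16 ± 0.15, limma p = 0.286) and fatty acid oxidation differed less (-0.12 ± 0.16, limma p = 0.452). The immediate-early and red cell lists below were then not under an unadjusted p of 0.05 (0.05 ± 0.07, limma p = 0.481, and 0.29 ± 0.14, limma p = 0.0511). The lists taken here as markers of handling and of blood moved with this comparison. Neither was checked against a record of handling. The immediate-early difference also went with leukocyte content, so these scores as covariates may remove differences that belong to the groups. The immediate-early and heat shock list rose by 0.30 ± 0.07 (adjusted p = 0.00363; adjusted p = 0.0674 with an estimated correlation), with 7 of 14 members higher (8 adjusted over the list alone). The red cell list rose by 0.25 ± 0.09 (adjusted p = 0.0242; adjusted p = 0.283 with an estimated correlation), with 0 of 6 members called. With these 2 scores as covariates 293 genes were called in place of 1992, and CXCL9, CXCL10 and JCHAIN had adjusted p of 0.249, 0.126 and 0.0635. Of the 6 genes with the largest falls 1, OLFM4, stayed under 0.05. The complement (adjusted p = 0.505), fatty acid oxidation (0.505), distal nephron (0.857), mast cell (0.12) and HLA class I (0.117) lists no longer passed. The tubular injury and repair list passed as lower in CAMR with these covariates (-0.49, adjusted p = 0.00596) and not without them (-0.09 ± 0.16, adjusted p = 0.722). Proximal tubule (-0.36 ± 0.26, adjusted p = 0.343) and podocyte (0.01 ± 0.09, adjusted p = 0.971) lists did not pass. Without the 4 arrays whose titles end in a code that no label explains (2 normal, 1 DSA-positive, 1 CAMR) 1014 genes and 16 lists passed. The B cell (0.0567), distal nephron (0.192) and red cell (0.0682) lists did not. Among the genes above, neither did CPA3 (0.153), FCER1A (0.15), SCARNA9 (0.0849), LYPLAL1 (0.0567), FMO5 (0.066), CD79A (0.0563), B2M (0.0648), KCNJ1 (0.0813) and HADHA (0.0546). There were 4597 calls with array weights, 2840 with the spread covariate, 2421 without the 7 narrow arrays and 2108 without the biopsy low in proximal tubule genes.

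**Figure D2:**
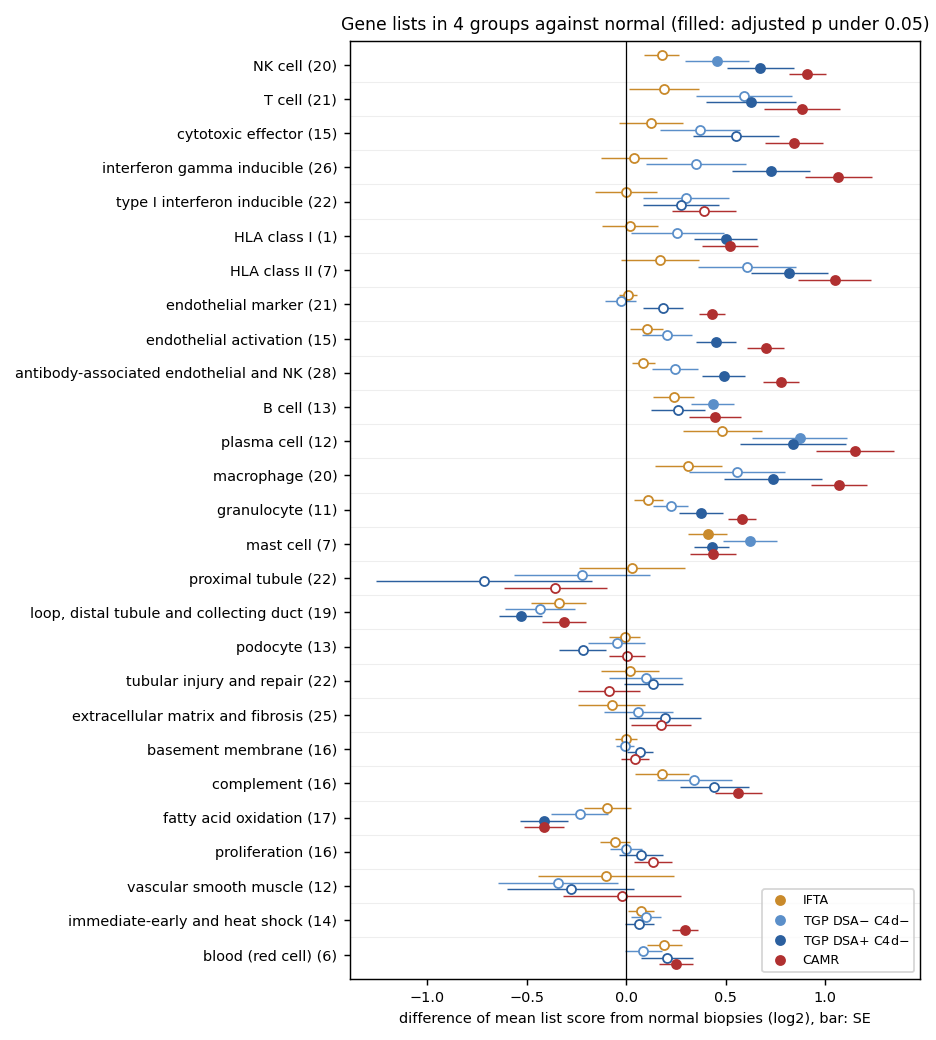
Difference of the mean list score of each of 4 groups from the normal biopsies on the log2 scale (horizontal axis, bars show the SE) for the 27 gene lists (rows, number of measured members in brackets), filled where adjusted p was under 0.05. The mast cell list is the single list filled in all 4 groups, and CAMR has 19 filled lists.

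DSA-positive, C4d-negative TGP was compared with normal transplants to ask what changes when antibody is found without C4d. The immunoglobulin genes JCHAIN (2.90 ± 0.81 on the log2 scale, 7.46-fold, adjusted p = 0.0321) and IGKC (1.96 ± 0.52, 3.88-fold, adjusted p = 0.0257) rose in these 9 biopsies. So did CXCL9 (3.77-fold), CXCL10 (3.12-fold), CXCL11 (3.62-fold), GBP5 (3.38-fold) and SLAMF7 (3.16-fold), with adjusted p from 0.016 to 0.0408. REG1A, a secreted lectin of regenerating epithelium, rose 3.13-fold (1.65 ± 0.44, adjusted p = 0.0262), above the normal mean in 7 of 9 biopsies. The 6 largest falls follow. APOH, a phospholipid-binding plasma protein, fell by 1.54 ± 0.44 (adjusted p = 0.0361) and the histidine-rich glycoprotein gene HRG by 1.22 ± 0.32. TMEM52B fell by 1.31 ± 0.33, TMEM207 by 1.28 ± 0.35 and the sulfatase gene ARSF by 1.17 ± 0.35. CLDN16, the paracellular magnesium channel of the thick ascending limb, fell by 1.03 ± 0.29 (adjusted p = 0.0321). limma called 708 genes, 349 higher and 359 lower, of which 273 changed at least 1.5-fold. With each array centred on its median the count was 758, of which 469 were higher and 289 lower. Without the 7 narrow arrays 601 genes were called, 456 higher and 145 lower, of which 370 were among the 708. Higher genes were also the majority in 6 other settings, so neither direction prevailed throughout. With array weights 3080 genes were called and with the spread covariate 1304.

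The NK cell, endothelial activation, antibody-associated, HLA class II and granulocyte lists rose in DSA-positive TGP. In the NK cell list 12 of 20 members rose (17 adjusted over the list alone), including FCGR3A (1.28 ± 0.26), SH2D1B (1.05 ± 0.24) and GNLY (0.93 ± 0.19), and the list rose by 0.67 ± 0.17 (adjusted p = 0.00259). The endothelial activation list rose by 0.45 ± 0.10 (adjusted p = 0.00108), with 4 of 15 members higher (7 adjusted over the list alone), including ACKR1 (1.18 ± 0.24) and SELE (1.06 ± 0.25). The antibody-associated list rose by 0.49 ± 0.11 (adjusted p = 0.000459). Of it 10 of 28 measured members rose, 1 fell and 17 were not called (16 higher and 1 lower when adjusted over the list alone), and the member that fell was SOST, an inhibitor of Wnt signalling. The endothelial marker list did not pass (0.19 ± 0.10, adjusted p = 0.143), with 2 of 21 members higher (5 adjusted over the list alone), among them ENG (0.34 ± 0.09), and it passed without the narrow arrays (0.29, adjusted p = 0.00674). HLA class II genes rose by 0.82 ± 0.20 (adjusted p = 0.00799), with 5 of 7 members higher (6 adjusted over the list alone), including HLA-DMB (0.77 ± 0.19) and HLA-DMA (0.76 ± 0.17). Granulocyte genes rose by 0.38 ± 0.11 (adjusted p = 0.0158), with 4 of 11 members higher (4 adjusted over the list alone), including AQP9 (0.84 ± 0.20) and FPR1 (0.60 ± 0.12).

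Several other lists passed the permutation test and not the test against all other genes. The interferon gamma list rose by 0.73 ± 0.20 (adjusted p = 0.011; adjusted p = 0.0773 with an estimated correlation), with 13 of 26 members higher (20 adjusted over the list alone), including PLA1A (1.02 ± 0.22). The macrophage list rose by 0.74 ± 0.24 (adjusted p = 0.0242; adjusted p = 0.0753 with an estimated correlation), with 7 of 20 higher (17 adjusted over the list alone), including CD86 (1.02 ± 0.25). T cell genes rose by 0.63 ± 0.23 (adjusted p = 0.0468; adjusted p = 0.111 with an estimated correlation), with 4 of 21 higher (17 adjusted over the list alone), including the kinase LCK (0.65 ± 0.15). Plasma cell genes rose by 0.84 ± 0.27 (adjusted p = 0.0227; adjusted p = 0.128 with an estimated correlation), with JCHAIN and IGKC the 2 of 12 members called (10 higher and 1 lower when adjusted over the list alone). B2M of the HLA class I list differed by 0.50 ± 0.16, which passed as a list (adjusted p = 0.0319). It did not pass in the camera test (adjusted p = 0.111) or over all genes (adjusted p = 0.0601, and 1 higher when adjusted over the list alone). Mast cell genes rose by 0.43 ± 0.09 (adjusted p = 0.00335; adjusted p = 0.05 with an estimated correlation), in 9 of 9 biopsies, with FCER1A (1.01 ± 0.27) the 1 of 7 members called (4 adjusted over the list alone). The distal nephron list fell by 0.53 ± 0.11 (adjusted p = 0.00146; adjusted p = 0.175 with an estimated correlation), with KCNJ1 (-0.63 ± 0.18) and CLDN16 lower (3 adjusted over the list alone). Fatty acid oxidation genes fell by 0.41 ± 0.12 (adjusted p = 0.00777; adjusted p = 0.227 with an estimated correlation), with HADHA (-0.36 ± 0.10) and ECI1 lower (9 adjusted over the list alone). Proximal tubule genes were lower by a mean that did not pass (-0.71 ± 0.54, adjusted p = 0.299), and without the biopsy at 6.72 the difference was -0.22 (adjusted p = 0.617).

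Without that biopsy 984 genes were called, 502 higher and 482 lower and 632 of them among the 708. APOH (adjusted p = 0.0605), TMEM207 (0.0617), CLDN16 (0.0738) and ARSF (0.0892) no longer passed. The cytotoxic effector (0.0102 in place of 0.0686), complement (0.00382 in place of 0.0574) and B cell (0.0496 in place of 0.143) lists passed without it. Without the 4 arrays with the unexplained title code 433 genes and 9 lists passed in place of 708 and 13. The T cell (0.116), macrophage (0.0742), HLA class I (0.0599) and plasma cell (0.0509) lists did not pass. JCHAIN (0.059), IGKC (0.0633), CXCL9 (0.0988) and CXCL10 (0.0658) did not either, nor did APOH (0.0642), TMEM207 (0.0641), HRG (0.0899), ARSF (0.118), CLDN16 (0.0719), KCNJ1 (0.148) and HADHA (0.0543). Without the narrow arrays 10 lists passed, and JCHAIN, IGKC and CXCL10 had adjusted p of 0.0815, 0.0903 and 0.0529. The T cell (0.0777), plasma cell (0.0615), granulocyte (0.0666) and HLA class I (0.0524) lists did not pass. The red cell (0.21 ± 0.13, adjusted p = 0.185) and immediate-early (0.07 ± 0.07, adjusted p = 0.515) lists did not pass in this comparison. With both scores as covariates 437 genes were called and the fatty acid oxidation list had an adjusted p of 0.0685, while the cytotoxic effector (0.0307) and complement (0.0298) lists passed. In the fit with T cell and macrophage scores the NK cell (0.28 ± 0.08, limma p = 0.00119), antibody-associated (0.26 ± 0.09, limma p = 0.00519) and granulocyte (0.20 ± 0.08, limma p = 0.0124) lists were under an unadjusted p of 0.05. The interferon gamma (0.20 ± 0.13, limma p = 0.133), HLA class II (0.18 ± 0.12, limma p = 0.133), endothelial activation (0.13 ± 0.08, limma p = 0.0902), plasma cell (0.30 ± 0.19, limma p = 0.114) and mast cell (0.23 ± 0.11, limma p = 0.0519) lists were not, nor were B2M (0.11 ± 0.13, limma p = 0.398), the distal nephron (-0.20 ± 0.14, limma p = 0.166) and fatty acid oxidation (-0.21 ± 0.15, limma p = 0.158) lists.

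In DSA-negative, C4d-negative TGP the mast cell, plasma cell, B cell and NK cell lists were higher than in normal transplants, with no single gene called. Mast cell genes rose by 0.62 ± 0.14 (adjusted p = 0.003), above the normal mean in 7 of 8 biopsies, with 5 of 7 members higher adjusted over the list alone. CPA3 differed by 1.85 ± 0.40 and FCER1A by 1.28 ± 0.28, each with an adjusted p of 0.0656 over all genes. Plasma cell genes rose by 0.87 ± 0.24 (adjusted p = 0.00917, 7 of 8 biopsies above the normal mean), with IGKC at 2.11 ± 0.54 (adjusted p = 0.115) and 8 of 12 members higher adjusted over the list alone. B cell genes rose by 0.43 ± 0.11 (adjusted p = 0.00716; adjusted p = 0.0676 with an estimated correlation) in 8 of 8 biopsies, with 6 of 13 members higher adjusted over the list alone and CD79A at 1.00 ± 0.41. NK cell genes rose by 0.46 ± 0.16 (adjusted p = 0.0242) in 7 of 8, with 10 of 20 members higher adjusted over the list alone, GNLY at 0.67 ± 0.19 and SH2D1B at 0.70 ± 0.25. T cell (0.59 ± 0.24, adjusted p = 0.0686) and cytotoxic effector (0.37 ± 0.20, adjusted p = 0.202) lists did not pass. Endothelial markers differed by -0.03 ± 0.08 (adjusted p = 0.825). The antibody-associated list differed by 0.25 ± 0.12 (adjusted p = 0.0834), with 7 members higher adjusted over the list alone, and the interferon gamma list by 0.35 ± 0.25 (adjusted p = 0.302).

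limma called 0 genes at an adjusted p under 0.05 with 8 biopsies against 12, and 1726 genes had an unadjusted p under 0.05. The immediate-early (0.10 ± 0.08, adjusted p = 0.342) and red cell (0.09 ± 0.09, adjusted p = 0.46) lists did not pass. Without the narrow arrays 1 gene and 5 lists passed, the antibody-associated list among them (0.31, adjusted p = 0.0195). When the DSA-positive biopsy low in proximal tubule genes was left out of the shared estimate of the spread, 12 genes were called. The distal nephron list, whose own difference and arrays that biopsy does not touch, passed as lower (adjusted p = 0.0496 in place of 0.0537) because the other tests in the adjustment changed. limma called 476 genes with array weights, 42 with the spread covariate, 12 in the fit of the 2 groups alone and 8 with centred arrays. Without the 4 arrays with the unexplained title code the NK cell list had an adjusted p of 0.0728. With T cell and macrophage covariates the mast cell (0.46 ± 0.11, limma p = 0.000158) and B cell (0.19 ± 0.10, limma p = 0.0495) lists were under an unadjusted p of 0.05, and the NK cell (0.13 ± 0.08, limma p = 0.104) and plasma cell (0.35 ± 0.19, limma p = 0.0629) lists were not.

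Few genes were called between IFTA, whose label names no glomerulopathy, and normal transplants. TYRP1, an enzyme of melanin synthesis, fell by 0.89 ± 0.17 (1.85-fold lower, adjusted p = 0.0485) and the zinc finger gene ZNF214 fell by 0.40 ± 0.08 (1.32-fold lower, adjusted p = 0.0485), both below the normal mean in 17 of 17 biopsies. These were the 2 genes that limma called, and 1355 had an unadjusted p under 0.05. Neither passed without the narrow arrays (adjusted p = 0.106 and 0.0996), and the count was also 0 in 5 other settings and 2 without the biopsy low in proximal tubule genes. It rose to 55 with array weights (18 higher, 37 lower) and to 5 with the spread covariate. The mast cell list was the 1 list to pass, rising by 0.41 ± 0.10 (adjusted p = 0.00368) in 16 of 17 biopsies, with 0 of 7 members called over all genes and 5 higher adjusted over the list alone. With T cell and macrophage covariates its difference was 0.33 ± 0.09, limma p = 0.000636. CPA3 differed by 1.30 ± 0.33 (adjusted p = 0.269) and the histamine-synthesising HDC by 0.24 ± 0.10 (adjusted p = 0.574). Plasma cell genes (0.48 ± 0.20, adjusted p = 0.0844) and the distal nephron list (-0.34 ± 0.14, adjusted p = 0.0834) did not pass. The immediate-early (0.07 ± 0.06, adjusted p = 0.451) and red cell (0.19 ± 0.09, adjusted p = 0.185) lists did not pass either.

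The calls in DSA-positive TGP and in CAMR overlapped. Of the 349 genes higher in DSA-positive TGP and the 1076 higher in CAMR, 320 were shared, 206 of the lower genes were shared, and 0 were called in opposite directions. Independent lists of these sizes would share 20.4 higher and 17.9 lower genes, which takes no account of the shared normal arrays. Simulated unchanged groups set against the same 12 normal arrays shared a mean of 0.3 and 0. Groups simulated without any change give few genes to call, so these counts are no chance level for lists of these sizes. Against separate sets of 6 normal arrays, a mean of 69.5 higher (0 to 192) and 5.2 lower (0 to 15) genes were shared over 20 random splits. Log2 fold changes of the 2 groups correlated across genes at r = 0.855 (simulated mean 0.326 and highest 0.804, split controls 0.676). The covariance was 0.0593, against a simulated mean of 0.00666 and highest of 0.0431, and 0.0518 with split controls. DSA-negative TGP correlated with DSA-positive TGP at r = 0.804 and with CAMR at r = 0.765 (split controls 0.55 and 0.539). Simulated unchanged groups gave means of 0.392 and 0.394 and ran from -0.682 to 0.877 and from -0.361 to 0.855, past these values. The simulations shared the normal arrays and drew whole arrays. Differences between whole arrays can thus add to such correlations beside the shared normal arrays. The covariances, 0.0388 and 0.042, lay above the highest simulated ones of 0.0306 and 0.0313, and were 0.0307 and 0.034 with split controls. These correlations run across genes, which are not independent replicates.

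CAMR was also compared with IFTA, the scarred transplants whose label names no glomerulopathy. CXCL11 rose by 2.65 ± 0.40 (6.29-fold, adjusted p = 1.46e-05), CXCL10 5.78-fold, CXCL9 5.04-fold and GBP5 4.3-fold, each in 11 of 11 biopsies. DSEL, an enzyme of dermatan sulfate synthesis, fell by 0.78 ± 0.23 (adjusted p = 0.0373) and the cytokine receptor IL17RB by 0.65 ± 0.19. The histidine catabolism gene AMDHD1 fell by 0.57 ± 0.16 and the carbonic anhydrase CA4 by 0.56 ± 0.13 (adjusted p = 0.00456). limma called 812 genes, 700 higher and 112 lower in CAMR, and 971, of which 677 were higher and 294 lower, with each array centred on its median. The interferon gamma list rose by 1.02 ± 0.15 (adjusted p = 0.000245), with 22 of 26 members higher (24 adjusted over the list alone), including PLA1A (1.17 ± 0.19). The antibody-associated list rose by 0.69 ± 0.10 (adjusted p = 0.000245), with 23 of 28 members higher (26 adjusted over the list alone). The endothelial marker list rose by 0.42 ± 0.07 (adjusted p = 0.000415, 13 of 21 higher, 16 adjusted over the list alone), with ROBO4 at 0.57 ± 0.09. Endothelial activation genes rose by 0.60 ± 0.11 (adjusted p = 0.000245, 8 of 15 higher, 10 adjusted over the list alone), with SELE at 1.30 ± 0.22. NK cell genes rose by 0.73 ± 0.09 (adjusted p = 0.000245, 14 of 20 higher, 17 adjusted over the list alone) and cytotoxic effector genes by 0.72 ± 0.12 (adjusted p = 0.00054, 10 of 15 higher, 15 adjusted over the list alone). Granulocyte genes rose by 0.47 ± 0.05 (adjusted p = 0.000245, 6 of 11 higher, 7 adjusted over the list alone). HLA class II genes rose by 0.88 ± 0.17 (adjusted p = 0.00187, 5 of 7 higher, 7 adjusted over the list alone).

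Another 8 lists passed against IFTA and not in the camera test. Macrophage genes rose by 0.76 ± 0.15 (adjusted p = 0.00146; adjusted p = 0.05 with an estimated correlation; 11 of 20 higher, 19 adjusted over the list alone). T cell genes rose by 0.69 ± 0.18 (adjusted p = 0.00657; adjusted p = 0.0765 with an estimated correlation; 11 of 21 higher, 19 adjusted over the list alone). Plasma cell genes rose by 0.67 ± 0.22 (adjusted p = 0.0309; adjusted p = 0.174 with an estimated correlation; 4 of 12 higher, 6 adjusted over the list alone). B2M rose by 0.50 ± 0.14 (list adjusted p = 0.00146, and adjusted p = 0.0999 in the camera test). Complement genes rose by 0.38 ± 0.13 (adjusted p = 0.0403; adjusted p = 0.213 with an estimated correlation; 4 of 16 higher, 8 adjusted over the list alone). Type I interferon genes rose by 0.39 ± 0.13 (adjusted p = 0.0342; adjusted p = 0.236 with an estimated correlation; 5 of 22 higher, 9 adjusted over the list alone), with OAS2 at 0.96 ± 0.21. The proliferation list rose by 0.19 ± 0.08 (adjusted p = 0.0243; adjusted p = 0.229 with an estimated correlation), with the spindle checkpoint kinase BUB1B (0.41 ± 0.08) the 1 of 16 members called (5 adjusted over the list alone). The immediate-early list rose by 0.22 ± 0.07 (adjusted p = 0.0255; adjusted p = 0.0766 with an estimated correlation; 4 of 14 higher, 8 adjusted over the list alone). The red cell list differed by 0.06 ± 0.11 (adjusted p = 0.758). With both scores as covariates 139 genes and 9 lists passed. These 9 were 8 of the lists above and the tubular injury and repair list, which was lower in CAMR (-0.42, adjusted p = 0.00682). CXCL9 had an adjusted p of 0.109, and DSEL, IL17RB, AMDHD1 and CA4 no longer passed. Neither did the macrophage (0.116), T cell (0.0731), plasma cell (0.0807), HLA class I (0.0605), complement (0.791), type I interferon (0.34) and proliferation (0.505) lists. Without the biopsy low in proximal tubule genes 858 genes were called, with array weights 2335 and with the spread covariate 1402. Without the 4 arrays with the unexplained code 568 genes and 11 lists passed. The type I interferon (0.06), plasma cell (0.0541), complement (0.0982), proliferation (0.0538) and immediate-early (0.0568) lists did not, nor did IL17RB (0.0757) and AMDHD1 (0.0672). Without the narrow arrays 922 genes and 13 lists passed, and DSEL and IL17RB had adjusted p of 0.0766 and 0.0759. In the fit with T cell and macrophage scores the complement list turned (-0.17 ± 0.06, limma p = 0.00705). The cytotoxic effector (0.16 ± 0.08, limma p = 0.0557), HLA class II (0.21 ± 0.11, limma p = 0.0569), plasma cell (0.07 ± 0.17, limma p = 0.686), type I interferon (0.13 ± 0.16, limma p = 0.446), proliferation (0.03 ± 0.08, limma p = 0.663) and immediate-early (0.05 ± 0.06, limma p = 0.372) lists and B2M (0.10 ± 0.12, limma p = 0.422) were not under an unadjusted p of 0.05. The NK cell (0.32 ± 0.07, limma p = 7.58e-05), interferon gamma (0.46 ± 0.12, limma p = 0.000242), endothelial marker (0.37 ± 0.08, limma p = 2.02e-05), endothelial activation (0.27 ± 0.07, limma p = 0.000273), antibody-associated (0.46 ± 0.08, limma p = 7.08e-07) and granulocyte (0.29 ± 0.07, limma p = 0.000135) lists were.

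DSA-positive TGP differed from IFTA in gene lists, while the number of single genes called depended on the setting. The antibody-associated list rose by 0.40 ± 0.11 (adjusted p = 0.00276, 9 of 9 biopsies above the IFTA mean; 16 higher and 1 lower when adjusted over the list alone), with SH2D1B at 0.88 ± 0.22 (adjusted p = 0.0939). The interferon gamma list rose by 0.69 ± 0.18 (adjusted p = 0.0055, 9 of 9; 20 of 26 higher adjusted over the list alone), with CXCL11 at 2.10 ± 0.43 (adjusted p = 0.0683). NK cell genes rose by 0.50 ± 0.17 (adjusted p = 0.00917, 8 of 9; 14 of 20 adjusted over the list alone), with FCGR3A at 1.05 ± 0.24. HLA class II genes rose by 0.65 ± 0.19 (adjusted p = 0.0242, 8 of 9; 6 of 7 adjusted over the list alone). The endothelial activation list rose by 0.35 ± 0.11 (adjusted p = 0.0243; adjusted p = 0.05 with an estimated correlation; 7 of 15 higher adjusted over the list alone). Granulocyte genes rose by 0.27 ± 0.10 (adjusted p = 0.0255; adjusted p = 0.0517 with an estimated correlation; 2 of 11 higher adjusted over the list alone). The HLA class I list, B2M, rose by 0.48 ± 0.13 (adjusted p = 0.00867, and adjusted p = 0.0734 in the camera test, with 1 higher adjusted over the list alone). limma called 0 genes, with 2436 at an unadjusted p under 0.05. It called 1491 with array weights, 284 with the spread covariate, 103 with the handling and red cell scores as covariates and 26 without the biopsy low in proximal tubule genes. It called 13 without the 4 arrays with the unexplained code, 2 with centred arrays, and 8 without the narrow arrays. In this last setting 5 lists passed in place of 7, among them the endothelial marker list. Some of the 7 lists above thus did not pass there. The cytotoxic effector and macrophage lists passed with the covariates (adjusted p = 0.0298 and 0.0282), these and the T cell list without that biopsy (0.0114, 0.0299 and 0.0217), and the endothelial marker list without the narrow arrays (0.0193). The immediate-early (-0.01 ± 0.07, adjusted p = 0.962) and red cell (0.02 ± 0.15, adjusted p = 0.954) lists did not pass. In the fit with T cell and macrophage scores all 7 lists that passed were under an unadjusted p of 0.05, from the NK cell (0.25 ± 0.07, limma p = 0.000868) to the HLA class I (0.25 ± 0.12, limma p = 0.0371) list.

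DSA-negative TGP and IFTA could not be separated by any gene or list. limma called 0 genes, with 307 at an unadjusted p under 0.05, and 0 of 27 lists passed. The smallest list p was that of NK cell genes (0.28 ± 0.16, unadjusted exact permutation p = 0.0486, adjusted p = 0.143), followed by T cell genes (0.40 ± 0.23, adjusted p = 0.192) and HLA class II genes (0.44 ± 0.24, adjusted p = 0.196). Endothelial markers differed by -0.04 ± 0.08 (adjusted p = 0.737).

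Within TGP, CAMR was set against the DSA-negative group, the clinical forms at both ends of the antibody findings. Among the 4 largest rises, TNFRSF9, a costimulatory receptor, rose by 1.16 ± 0.23 (2.24-fold, adjusted p = 0.0127) and the adhesion receptor ADGRE1 by 1.06 ± 0.19 (2.09-fold, adjusted p = 0.00405). FCN1, a ficolin of monocytes, rose by 1.03 ± 0.22 (adjusted p = 0.0208) and the integrin ITGAX by 1.02 ± 0.24 (adjusted p = 0.037). The 1 gene that fell was FLRT3, an adhesion protein, by 0.52 ± 0.13 (adjusted p = 0.0425), and all 5 lay on that side of the DSA-negative mean in 11 of 11 biopsies. The endothelial marker list rose by 0.46 ± 0.09 (adjusted p = 0.00132): 7 of 21 measured members rose, 0 fell and 14 were not called (16 higher and 0 lower when adjusted over the list alone). The 7 were CDH5, ESAM, ROBO4, PLVAP, MMRN2, ENG and NOS3, with ROBO4 at 0.61 ± 0.10 and ENG at 0.47 ± 0.10. The endothelial activation list rose by 0.50 ± 0.14 (adjusted p = 0.011), with PLAT and MALL the 2 of 15 members called (10 adjusted over the list alone). The antibody-associated list rose by 0.53 ± 0.14 (adjusted p = 0.00917), with 4 of 28 called (20 adjusted over the list alone). Granulocyte genes rose by 0.36 ± 0.08 (adjusted p = 0.000298; FPR2 called, 5 of 11 adjusted over the list alone). Interferon gamma genes rose by 0.71 ± 0.24 (adjusted p = 0.02; WARS1 and CALHM6 called, 21 of 26 adjusted over the list alone). NK cell genes rose by 0.46 ± 0.16 (adjusted p = 0.0248; 0 of 20 called, 8 adjusted over the list alone). Cytotoxic effector genes rose by 0.48 ± 0.17 (adjusted p = 0.0243; adjusted p = 0.0773 with an estimated correlation; 0 of 15 called, 6 adjusted over the list alone). T cell (0.29 ± 0.24, adjusted p = 0.398), macrophage (0.51 ± 0.23, adjusted p = 0.0626) and plasma cell (0.28 ± 0.26, adjusted p = 0.446) lists did not pass, with 0 members called in each.

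In this comparison limma called 53 genes, 52 of them higher in CAMR, 64 without the narrow arrays and 62 without the biopsy low in proximal tubule genes. Without the narrow arrays 6 lists passed in place of 7, and also 6 without members shared between lists. The immediate-early list was higher by 0.20 ± 0.08 (adjusted p = 0.0834) and the red cell list by 0.16 ± 0.11 (adjusted p = 0.33), which did not pass. With both scores as covariates 0 genes were called by limma. The endothelial marker (0.37, adjusted p = 0.0012), endothelial activation, antibody-associated and granulocyte lists stayed past the threshold with these covariates. The NK cell (0.151), cytotoxic (0.331) and interferon gamma (0.0605) lists did not. The tubular injury and repair (-0.45, adjusted p = 0.0121) and mast cell (-0.31, adjusted p = 0.0371) lists passed as lower in CAMR in this setting. In the fit with T cell and macrophage scores all 7 lists that passed were under an unadjusted p of 0.05, from the endothelial marker (0.39 ± 0.09, limma p = 2.91e-05) to the cytotoxic effector (0.20 ± 0.09, limma p = 0.0282) list. Fitted on the 2 groups alone, 3 genes were called, with array weights 253 and with the spread covariate 138. Without the 4 arrays with the unexplained title code 18 were called, and FCN1 (0.0529), ITGAX (0.089), FLRT3 (0.0606), NOS3 (0.0873), MALL (0.0712) and FPR2 (0.108) were not.

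CAMR was compared with DSA-positive TGP, from which it differs in C4d. limma called 0 genes, with 815 at an unadjusted p under 0.05, and 1 gene, lower in CAMR, with handling and red cell covariates. The 1 list that passed was the immediate-early and heat shock list, taken here as a marker of handling. It was higher in CAMR by 0.23 ± 0.08 (adjusted p = 0.0317), with 0 of 14 members called (5 adjusted over the list alone). With T cell and macrophage covariates the list differed by 0.15 ± 0.06 (limma p = 0.0176). Its adjusted p was 0.0742 without the 4 arrays with the unexplained code, 0.0694 without the narrow arrays, where the granulocyte list passed in its place (adjusted p = 0.0133), and 0.0578 without the biopsy low in proximal tubule genes, where the endothelial marker list passed (0.29, adjusted p = 0.0429). The endothelial marker (0.25 ± 0.11, adjusted p = 0.108), antibody-associated (0.29 ± 0.13, adjusted p = 0.132), granulocyte (0.21 ± 0.10, adjusted p = 0.107) and interferon gamma (0.34 ± 0.18, adjusted p = 0.185) lists did not pass. With an estimated correlation the endothelial marker list passed (adjusted p = 0.0391), and with handling and red cell covariates the tubular injury and repair list passed as lower in CAMR (-0.54, adjusted p = 0.00193).

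The DSA-positive and DSA-negative forms of C4d-negative TGP were compared to ask what the presence of antibody adds. limma called 0 genes, with 413 at an unadjusted p under 0.05, and 0 of 27 lists passed the permutation test, adjusted or not. Endothelial markers differed by 0.21 ± 0.12 (adjusted p = 0.232), endothelial activation genes by 0.25 ± 0.15 (adjusted p = 0.239), interferon gamma genes by 0.38 ± 0.26 (adjusted p = 0.3) and mast cell genes by -0.19 ± 0.13 (adjusted p = 0.285). With an estimated correlation the endothelial marker (adjusted p = 0.0358) and antibody-associated (0.0465) lists passed as higher in the DSA-positive group. With handling and red cell covariates the endothelial marker (0.0414), endothelial activation (0.00998) and antibody-associated (0.0163) lists did. With 9 biopsies against 8, the test found 92% of simulated 2-fold changes and 64% of 1.5-fold changes, in simulations where genes vary independently. In other comparisons above, some single genes that differed by more than 2-fold were not called. Differences of either size could thus be missed.

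**Figure D3:**
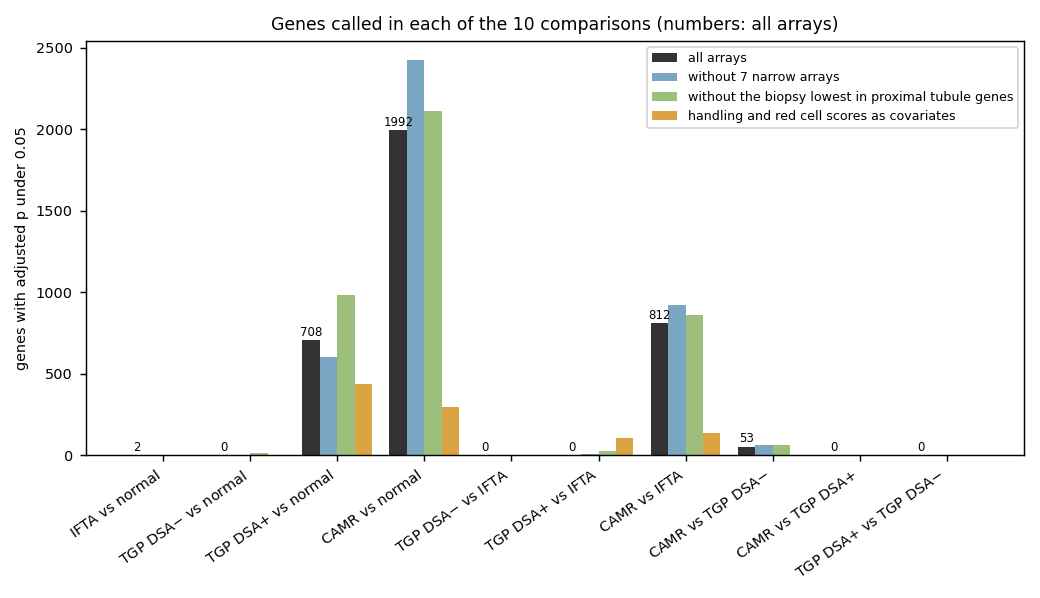
Number of genes with adjusted p under 0.05 (vertical axis) in each of the 10 comparisons (horizontal axis), with all arrays and in 3 other settings shown as bars of different colours. With all arrays CAMR against normal gave 1992 genes, and 293 with the handling and red cell scores as covariates.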

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

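In the DSA-negative and DSA-positive TGP groups 73 values were tested for a biopsy far from the others of its group. Of these 8 stood out, where chance flags about 1 in 20. Each value is the gap to the nearest biopsy as a share of the group's range. A single DSA-positive biopsy gave 6 of the 8: it was lowest in the proximal tubule list (6.72 against 10.8 in the next, gap 0.827), the macrophage list (7.31 against 8.54, gap 0.516), the complement list (8.69 against 9.47, gap 0.496), JCHAIN (4.85 against 8.74, gap 0.517), TMEM52B (6.17 against 9.90, gap 0.768) and CLDN16 (7.18 against 10.1, gap 0.721). In the DSA-negative group 1 biopsy was lowest in the endothelial marker list (7.69 against 8.03, gap 0.543) and another in the proximal tubule list (9.41 against 10.8, gap 0.561). No explanation of these 8 values was tested. The larger normal, IFTA and CAMR groups were not tested for such biopsies. In the proximal tubule list 1 normal biopsy was at 9.42, against 11.1 in the next lowest of its group. In IFTA 1 biopsy was at 8.86, against 10.9 in the next lowest.

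For the higher immune and endothelial lists of CAMR against normal, the tests without narrow arrays and against the podocyte score were chosen after seeing the results. The covariates of the third were chosen before the data were examined, and taken as a test of this after their results had been seen. The narrow CAMR arrays scored 7.37 and 7.79 in the antibody-associated list, both under the CAMR mean, and 0 normal arrays were narrow. Leaving them out could therefore only raise the difference, which was then 0.859 (adjusted p = 0.000115). The narrow arrays thus did not produce the difference, while signal spread among the other arrays is not tested by this. The endothelial marker score minus the podocyte score was higher in CAMR by 0.425 (permutation p = 0.00094, 11 of 11 biopsies). This test assumed that a smaller share of tubule in the core would not raise that score. The DSA-positive biopsy at 6.72 in the proximal tubule list scored 8.73 for endothelial markers and 7.4 for podocytes. The normal biopsy at 9.42 scored 8.36 and 7.58, and a DSA-negative biopsy at 9.41 scored 8.315 and 8.109. The podocyte test therefore cannot set tubule share aside. With the immediate-early and red cell scores as covariates the antibody-associated list differed by 0.509 (adjusted p = 8.41e-05 in the limma fit) in place of 0.777. Part of the difference may thus go with handling or blood.

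For the mast cell list, the pooled and tubule tests were written before and the test without narrow arrays after seeing their results. All 45 other biopsies together were higher than the 12 normal ones by 0.458 (permutation p = 1e-05, the smallest these resamples can give; 43 of 45 above the normal mean), but each of the 4 groups had already passed against the same 12 normal biopsies, so this test could only pass. Whether these 12 were low by chance stays open. The mast cell score minus the mean of the podocyte, endothelial marker and smooth muscle scores was higher in IFTA by 0.442 (permutation p = 0.00207, 16 of 17). Without the narrow arrays the list passed in 4 of 4 comparisons with normal. In CAMR the list had an adjusted p of 0.12 with handling and red cell covariates, and a difference of 0.14 (limma p = 0.237) with T cell and macrophage scores.

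For the endothelial marker list in CAMR against DSA-negative TGP, the leukocyte and tubule tests were written before and the test without narrow arrays after seeing their results. With the T cell and macrophage scores as covariates the list differed by 0.394 (limma p = 2.91e-05) in place of 0.458. The score minus the podocyte score was higher in CAMR by 0.405 (exact p = 0.00271, 10 of 11 biopsies). Without the narrow arrays the difference was 0.444 (adjusted p = 0.00148). The difference thus remained with T cell and macrophage scores held and without the narrow arrays. NK cell and granulocyte scores, which also differed in this comparison, were not among the covariates. Leaving out narrow arrays does not cover signal spread among the other arrays. The podocyte test cannot set tubule share aside, for the reason given for CAMR against normal. The antibody and C4d findings that separate the groups remain a possible cause, which was not tested directly.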

How the results depend on the processing

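No result past its threshold turned its direction under the alternatives named here, although the direction of the majority of calls did. For CAMR against normal it turned from higher to lower with median centring, the 2 groups alone, array weights and the dim filter. For DSA-positive TGP against normal (349 higher, 359 lower) it turned to higher with the 2 groups alone, centring, the averaged pair, handling covariates and the 1.5-fold filter. It also did so without narrow arrays, without the lowest biopsy and with the spread covariate. In the separate fit with T cell and macrophage scores, the complement list turned in CAMR against normal (-0.21, limma p = 0.00288) and against IFTA (-0.17, limma p = 0.00705). The distal nephron list (0.16, limma p = 0.286) and B2M (-0.04, limma p = 0.775) also turned in CAMR against normal. Of 249 alternatives for 22 counts and overlaps, 186 were the same, 30 weaker and 33 stronger; of 2408 for 223 named genes, 2139, 178 and 91; of 3220 for 270 lists, 3060, 105 and 55. Counts below are genes called, with the count of all arrays first; the cause was not tested unless it is given. Fewer biopsies can lower the power in the fits on 2 groups and in those that leave arrays out, and a fold filter can only remove genes.

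IFTA against normal (2): 2 groups alone 0, array weights 55, dim filter 1, median centring 0, without the 4 arrays with the unexplained code 0, averaged pair 0, handling and red cell covariates 0, 1.5-fold 1, without narrow arrays 0, spread covariate 5. DSA-negative TGP against normal (0): 2 groups alone 12, weights 476, centring 8, without narrow arrays 1, without the biopsy lowest in proximal tubule genes 12, spread covariate 42. DSA-positive TGP against normal (708): weights 3080, without the unexplained code 433, handling covariates 437, 1.5-fold 273, spread covariate 1304. CAMR against normal (1992): weights 4597, without the unexplained code 1014, handling covariates 293, 1.5-fold 650. DSA-positive TGP against IFTA (0): weights 1491, centring 2, without the unexplained code 13, handling covariates 103, without narrow arrays 8, without the lowest biopsy 26, spread covariate 284. CAMR against IFTA (812): weights 2335, handling covariates 139, 1.5-fold 347, spread covariate 1402. CAMR against DSA-negative TGP (53): 2 groups alone 3, weights 253, without the unexplained code 18, handling covariates 0, 1.5-fold 31, spread covariate 138. CAMR against DSA-positive TGP (0): handling covariates 1. Any difference among the 5 groups (1083): without the unexplained code 678, weights 3888, spread covariate 1854.

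Lists past the threshold: DSA-negative TGP against normal (4), spread covariate 9; DSA-positive TGP against normal (13), camera 5; CAMR against normal (19), camera 9; DSA-positive TGP against IFTA (7), camera 4; CAMR against IFTA (16), handling covariates 9 and camera 8. CAMR against DSA-positive TGP (1) gave 0 with the dim filter, 0 with centring, 0 without the unexplained code, 3 with the spread covariate and 2 with camera. DSA-positive against DSA-negative TGP (0) gave 1 with centring, 1 with the median over members, 3 with handling covariates, 2 with the spread covariate and 2 with camera. DSA-positive TGP and CAMR shared 526 genes, and new calls against separate sets of 6 normal arrays, with fewer arrays in each comparison, shared a mean of 74.7.

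The spread covariate and the settings around narrow arrays and the lowest biopsy were chosen after seeing the data. No paired analysis was possible because no title number is shared between groups. Signal over background was not recorded, and the dim filter kept 12533 genes.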

Other observations

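The tests with random regroupings were written before the results were seen. Each count of calls was compared with 99 random regroupings of the same arrays, and the number of 100 groupings, the real one included, with as many calls was 1 for CAMR against normal (1992 real, highest other 0) and 1 for DSA-positive TGP against normal (708, highest other 101). It was 2 for IFTA against normal (2, highest other 5), 2 for CAMR against IFTA (812, highest other 2921), 2 for CAMR against DSA-negative TGP (53, highest other 1716) and 3 for any difference among the 5 groups (1083, highest other 3476). Where 0 genes were called every grouping has as many (100), which decides nothing about chance; the highest others there were DSA-negative TGP against normal (2), DSA-negative TGP against IFTA (1), DSA-positive TGP against IFTA (8009), CAMR against DSA-positive TGP (5240) and DSA-positive against DSA-negative TGP (1736). In the random grouping with 8009 calls the mean interquartile range of the arrays differed between the groups by 0.406, against 0.0816 in the real one, and in that with 5240 by 0.347 against 0.0325. These were the groupings with the largest such difference. Those with 2921, 1716 and 1736 calls ranked 2, 4 and 8 in it among the regroupings of their comparison, and that with 101 calls ranked 8. Groupings with many calls thus point to a structure of the arrays in signal spread, although calls did not follow it strictly.

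Some lists passed in no comparison by the permutation test on all arrays. Against normal, CAMR differed by -0.36 ± 0.26 in proximal tubule genes (adjusted p = 0.343), 0.01 ± 0.09 in podocyte genes (0.971), -0.09 ± 0.16 in tubular injury and repair genes (0.722), 0.18 ± 0.15 in extracellular matrix and fibrosis genes (0.446), 0.04 ± 0.07 in basement membrane genes (0.666) and -0.02 ± 0.30 in vascular smooth muscle genes (0.964). IFTA differed from normal by -0.07 ± 0.17 in extracellular matrix and fibrosis genes (adjusted p = 0.792) and by 0.02 ± 0.15 in tubular injury genes (adjusted p = 0.954). With the T cell and macrophage scores as covariates the tubular injury and repair list was lower in CAMR than in normal biopsies (-0.58, limma p = 8.6e-05), IFTA (-0.44, limma p = 0.000503), DSA-negative TGP (-0.46, limma p = 0.000889) and DSA-positive TGP (-0.38, limma p = 0.00293). These p-values are not adjusted, and the T cell and macrophage scores themselves were higher in CAMR than in normal biopsies and in IFTA.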
